A study of Mus musculus with 2 samples.

How the data were processed

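Total RNA of washed platelets from Smad4 f/f mice and from Smad4 −/− mice was amplified and biotin-labelled with a 3' in vitro transcription kit and hybridised to Affymetrix whole-genome mouse arrays, per the labels. Each genotype has 1 array and 6 mice, and whether the RNA of the mice was pooled is not given in the sources used here. The deposited values are log2 signals, 1 per probe set and array. MAS5, which summarises the probes of a set and scales each array to a common level, is named per the submitters' processing notes, with no version or setting. The scale and the scaling were read from the values: the antilogs have a mean of 500.01 on both arrays after trimming 2% at each end, and the median log2 values of the arrays are 6.71 for Smad4 f/f and 6.61 for Smad4 −/−. Detection calls were not used here.

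Of 45101 probe sets, 64 are controls. Of the other 45037, 34945 have 1 gene symbol, 932 have several and 9160 have none in the platform annotation used, which can be out of date. Probe sets with several symbols or none were left out of the gene values. Symbols were looked up through Entrez gene IDs in a RefSeq gene table of the GRCm38.p6 assembly, where 34741 probe sets matched and 0 symbols changed. That table was also used for the order of genes around Pf4, and no genome sequence was used. The annotated probe sets cover 18193 genes.

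Values were used as the authors scaled them. Signals were raised to a floor, the higher of the 60th percentiles of the 2 arrays over probe sets that are not controls, a log2 signal of 7.18 or a linear signal of 145. A gene counted as measured if at least 1 array reached the floor, which held for 11089 genes. Each gene took the value of its probe set with the highest mean log2 signal, and probe sets ending in _x_at only where there was no other. All ratios are Smad4 −/− over Smad4 f/f on floored log2 values, and a fold with 1 side below the floor is a lower bound, written as at least that fold. The log2 ratios given for Acvr2b, Tgfbi, Vav3, Usp18, Dnajb1, H3f3a, Mpeg1, Erg and Hk2 also have 1 side at the floor and are bounds in the same way. With 1 array per genotype no test was run and no p-value or error of a group is given; a 2-fold difference serves only as a rule of size. The SD of the log2 ratio between measured probe sets of the same gene, pooled over genes, stands as a technical yardstick.

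Genes were named by a fixed rule. Smad4, Syk, Rock1, Rock2 and Rhoa were always named. To these came the 12 genes with the highest and the 12 with the lowest ratio among those that passed 2-fold, reached the 75th percentile of signal (log2 8.02) on at least 1 array and had all measured probe sets in the same direction, without predicted genes and unnamed clones; 311 genes met this rule on the higher side and 304 on the lower. A gene with 1 measured probe set meets the condition on direction by itself. In each gene list up to 4 measured members with the largest ratios were named. Where no member passed 2-fold, the 2 with the highest signal were named. Car2 and Slc4a1 fall outside this rule and were named after their values were seen, as were the strongly expressed genes of the closing section.

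The 30 gene lists cover TGF-beta and BMP signalling and SMAD targets, platelet functions (receptors, granule cargo, ITAM and Syk signalling, the cytoskeleton, granule secretion, eicosanoids, apoptosis), megakaryocyte transcription factors, general processes (ribosome, oxidative phosphorylation, glycolysis, proteasome, histones, cell cycle, interferon, immediate early and stress responses), the chemokine genes around Pf4, sex-linked transcripts, and markers of other cells (erythroid, B cell, T and NK cell, monocyte, neutrophil, basophil, MHC class II and endothelial). The ribosomal, oxidative phosphorylation, proteasome and histone lists were taken by symbol pattern and the others gene by gene. The result of 1 of the lists is not reported here. For each list with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size drawn from measured genes in 20 bins of mean signal. The groups, the floor, the size rule, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where said otherwise.

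Alternatives were median centring, quantile normalisation and a loess correction of the ratio on signal, a floor at the 50th or 75th percentile or none, the mean of a gene's measured probe sets, leaving out probe sets ending in _s_at or _x_at, thresholds of 1.5-fold and 3-fold, and counting only genes whose probe sets go the same way. Array quality was read from control probe sets. The 3' over 5' signal was 1.86 in Smad4 f/f and 2.61 in Smad4 −/− for Gapdh, and 1.16 and 1.27 for beta-actin. The hybridisation spike-ins BioB, BioC and BioD had a median log2 ratio of 0.20, the Cre spike-in 0.07 and the poly-A spike-ins −0.095.

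The steps were tested on simulated data for this comparison, with noise of the size seen between the 2 arrays at each signal level. Of 100 genes simulated at 3-fold, 80 passed 2-fold in the right direction, and of 100 at 4-fold, 92 did. Of 11089 unchanged genes, 732 (6.6%) also passed 2-fold, against 7.0% of genes in the real arrays; the noise was set from the real ratios, so the nearness of these shares follows from the construction and gives no error rate. Of 200 unchanged lists of 25 genes, 10 fell outside the central 95%. These lists were drawn from the same simulated genes as the random lists, so a share near that follows from the construction. Of 100 lists of 25 genes shifted by 0.3 on the log2 scale, 71 lay above the central 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.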

Results

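Gene expression was measured in washed platelets of C57BL/6 mice whose Smad4 gene is flanked by loxP sites (Smad4 f/f) and of mice in which a Cre recombinase driven by the platelet factor 4 promoter removes Smad4 in megakaryocytes and platelets (Smad4 −/−). Smad4 is the shared partner of the receptor-regulated SMAD proteins in TGF-beta and BMP signalling, and platelets, which have no nucleus, carry mRNA made in the megakaryocyte. The comparison asks which platelet transcripts differ with the loss of Smad4. The labels give 6 mice per genotype, and there is 1 array per genotype, so there are no replicates. Every difference below is a difference between 2 arrays, with no test, and the number of arrays limits the precision. Of 45037 probe sets that are not controls, 18015 (40.0%) lay at or above the signal floor in Smad4 f/f and 17361 (38.6%) in Smad4 −/−. Signals across the 13999 probe sets above the floor on both arrays correlated with a Pearson r of 0.973 and a Spearman coefficient of 0.917, a correlation across probe sets, which are not independent replicates. The median log2 ratio over these probe sets was −0.01, and 11089 genes counted as measured.

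The signal of Smad4 itself was nearly the same on both arrays. Its strongest probe set read 949 in Smad4 f/f and 894 in Smad4 −/−, a log2 ratio of −0.09, and its other probe sets gave −0.12 and −0.13. A probe set outside the deleted part of a gene cannot check the genotype, and the place of these 3 probe sets within Smad4 was not analysed here. The labels state that the loss was checked at the protein level.

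Syk, the tyrosine kinase that carries signals of the collagen receptor, C-type lectin receptor and integrins in platelets, read 5571 in Smad4 f/f and 2586 in Smad4 −/−, 2.15-fold lower. Its probe sets did not all go the same way. The second strongest gave a log2 ratio of −0.73 and of 2 weak ones, 1 was at least 2.01-fold lower and the other at least 2.06-fold higher in Smad4 −/−. The mean log2 ratio of the 4 was −0.45, short of 2-fold. All 4 measured probe sets of Rock1, a kinase that acts on myosin, were lower in Smad4 −/−, with log2 ratios of −0.21, −0.55, −0.56 and −1.39. The strongest of them, taken as the value of the gene, read 4297 against 3706. Rhoa, a small GTPase of the cytoskeleton, read 30535 in Smad4 f/f and 24911 in Smad4 −/−, a log2 ratio of −0.29, and its second measured probe set gave −0.53. Rock2 was not analysed here.

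**Figure D1:**
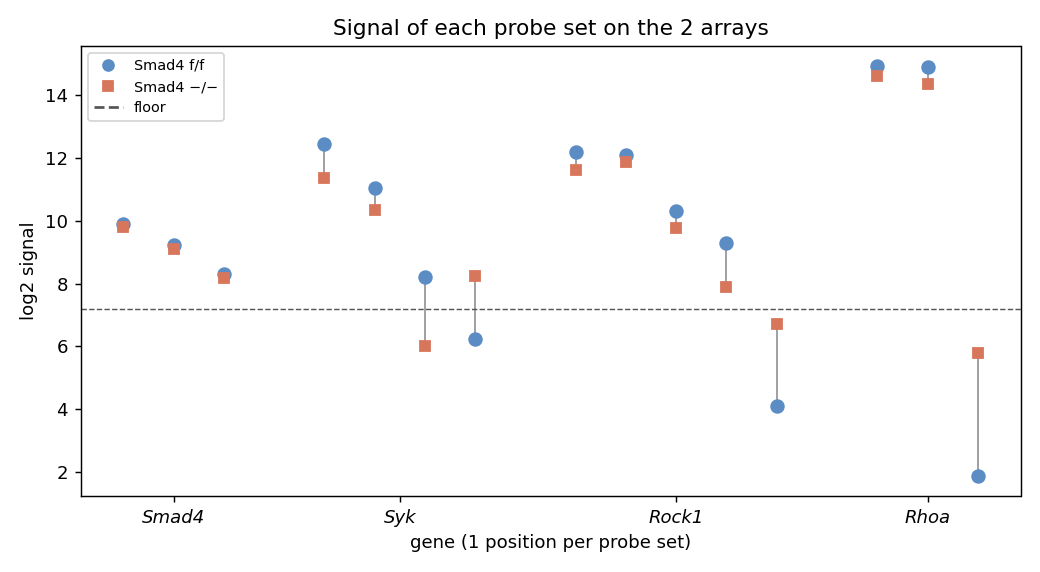
Log2 signal of each probe set of Smad4, Syk, Rock1 and Rhoa on the Smad4 f/f array (circles) and the Smad4 −/− array (squares), with the floor of 7.18 as a dashed line. The 3 Smad4 probe sets have log2 ratios from −0.13 to −0.09, and 1 of the weak Syk probe sets runs against the other 3.

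Across all measured genes, 379 were at least 2-fold higher in Smad4 −/− and 397 at least 2-fold lower, while 10313 lay within 2-fold. The gene with the highest ratio was Rab6b, a small GTPase of Golgi transport, which read 246 in Smad4 f/f and 3502 in Smad4 −/−, 14.3-fold higher. Its 4 measured probe sets had log2 ratios from 1.80 to 4.04. Agreement in direction was a condition for naming such genes and no separate support. Dut, which removes dUTP from the nucleotide pool, was 8.45-fold higher (1263 against 10669.9), and Cd59a, an inhibitor of the complement membrane attack complex, was 7.82-fold higher (1192 against 9319). The other measured probe sets of Dut and Cd59a had log2 ratios of 1.62 and 3.24. The largest differences in the other direction among strongly expressed genes included Cd226, an adhesion receptor of platelets and lymphocytes. It has 1 probe set, which read 15351 in Smad4 f/f and 3035 in Smad4 −/−, 5.06-fold lower.

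Among the other genes with the highest ratios, Ppil1, a peptidyl-prolyl isomerase of the spliceosome, was at least 10.4-fold higher in Smad4 −/−, with the Smad4 f/f signal of 131 below the floor. Ddb1, a DNA damage-binding subunit of ubiquitin ligases, was 6.15-fold higher, Loxl1, a cross-linking enzyme of elastic fibres, 5.82-fold and Ndrg2 5.71-fold. Bace1, the beta-secretase, was at least 5.65-fold higher, and Pmm1, a phosphomannomutase, at least 4.86-fold. Other measured probe sets went as low as log2 ratios of 0.41 for Bace1 and 0.30 for Pmm1, short of 2-fold. The other measured probe set of Loxl1 had a log2 ratio of 1.52. Chsy1, a chondroitin synthase, was 4.34-fold higher and the chemokine gene Cxcl3 4.29-fold. The histone H3 gene H3c11 was 4.13-fold higher, reading 8050.04 against 33214. Ppil1, Ddb1, Ndrg2, Chsy1, Cxcl3 and H3c11 had 1 measured probe set each.

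Ctdspl2 was at least 10.2-fold lower in Smad4 −/− (1482 against a signal below the floor), and Tfec, a transcription factor of the MiT family, was 8.39-fold lower (1858 against 221). Syne4, which links the nuclear envelope to microtubule motors, was 4.94-fold lower and Clstn1, a calsyntenin, 4.88-fold. The other measured probe sets of Ctdspl2 and Syne4 had log2 ratios of −1.14 and −1.03, but that of Clstn1 one of only −0.12. Uqcc1, an assembly factor of respiratory complex III, was 4.11-fold lower. Fbxo6 was at least 4.56-fold lower, the homeobox gene Cux2 at least 4.35-fold, the transcriptional repressor Cic at least 3.995-fold and Ppme1, which demethylates protein phosphatase 2A, at least 3.95-fold. Plekhg5 and Npy, which encodes neuropeptide Y, read 566 and 564 in Smad4 f/f and lay below the floor in Smad4 −/−. The other measured probe set of Cux2 had a log2 ratio of −0.79, short of 2-fold. Tfec, Uqcc1, Fbxo6, Cic, Ppme1, Plekhg5 and Npy had 1 measured probe set each.

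Probe sets of one gene give a technical yardstick for these single ratios. Over 4252 genes with 2 or more measured probe sets, the pooled SD of the log2 ratio within a gene was 0.48. Where the strongest probe set passed 2-fold, the next one had the same sign in 180 of 286 genes, and in 48 of 53 genes when both had a mean log2 signal of 9 or more. This yardstick holds no spread between animals or arrays, so the 2-fold counts cannot be set against the spread within a genotype. The counts also move with the floor, to 671 higher and 762 lower at the 50th percentile and to 175 and 140 at the 75th.

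**Figure D2:**
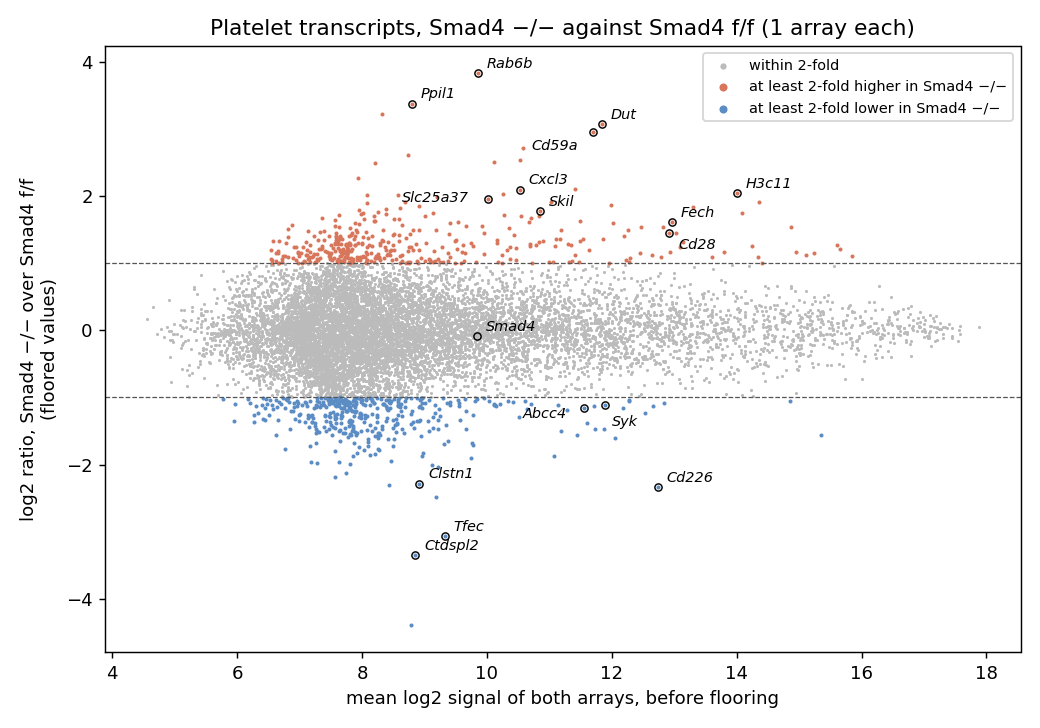
Log2 ratio of Smad4 −/− over Smad4 f/f on floored values (vertical axis) against the mean log2 signal of both arrays (horizontal axis), with 1 point per measured gene and dashed lines at 2-fold. The 379 genes at least 2-fold higher and the 397 at least 2-fold lower are coloured, Rab6b has the highest ratio at 3.83, and Smad4 lies close to 0.

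Genes of TGF-beta and BMP signalling and SMAD targets can be set beside all measured genes, of which 7.0% passed 2-fold. In the pathway list, 2 of 25 measured genes were at least 2-fold higher in Smad4 −/− and 0 were lower. Skil, which encodes the SMAD repressor SnoN, read 996 in Smad4 f/f and 3421 in Smad4 −/−, 3.43-fold higher. That rests on 1 measured probe set, and the other Skil probe set lay below the floor on both arrays (128 against 9). Smad5 was 2.53-fold higher with 3 probe sets in the same direction, whose mean log2 ratio of 0.73 is short of 2-fold. The activin receptor genes Acvr2a and Acvr2b had log2 ratios of 0.81 and 0.85. Of 15 measured SMAD target genes, which share Ski and Skil with the pathway list, 2 were at least 2-fold higher and 1 was lower. Cdkn1a, a cell cycle inhibitor, was at least 2.68-fold higher, the fibronectin gene Fn1 was 2.08-fold lower, and Tgfbi had a log2 ratio of 0.87. The list medians were 0.04 and −0.003, at percentiles 69.2 and 49.5 of random lists of matched signal.

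Among platelet adhesion and agonist receptors, 2 of 30 measured genes were at least 2-fold lower in Smad4 −/− and 0 higher. Beside Cd226, the thromboxane receptor gene Tbxa2r was at least 2.90-fold lower. P2ry1, an ADP receptor, had a log2 ratio of −0.83 and Pecam1 one of 0.92. Granule cargo went both ways, with 2 of 26 genes higher and 2 lower. Abcc4, a transporter of dense granules, was 2.22-fold lower (4495 against 2023), and the chemokine genes Cxcl5 and Ccl5 were 2.09-fold and 2.02-fold higher. Aplp2 was 2.04-fold lower by its strongest probe set, but its 4 measured probe sets disagreed and their mean log2 ratio was 0.27. The medians of the receptor and cargo lists lay at percentiles 26.3 and 85.0.

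In the list of ITAM, Syk and integrin signalling, Syk, by its strongest probe set, was the only one of 49 measured genes past 2-fold. Plcg2, the phospholipase downstream of Syk, had a log2 ratio of −0.97, Vav3 one of −0.92 with Smad4 −/− below the floor, and Btk one of 0.80. The list median was −0.02, at percentile 34.0.

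None of the 37 measured genes of the actin and microtubule cytoskeleton passed 2-fold, and Tmsb4x and Actb, near the top of the signal scale, had log2 ratios of 0.10 and 0.15. The list median was 0.10, at percentile 92.7, but −0.09 at percentile 8.47 with the mean of each gene's probe sets. The 34 genes of granule biogenesis and secretion also stayed within 2-fold, with a median of −0.14 at percentile 4.17, but −0.007 at percentile 49.8 with no floor; Snap23 and Stx11, its strongest members, had log2 ratios of 0.03 and −0.19. For the 11 genes of eicosanoid synthesis, also within 2-fold, the median was −0.25 at percentile 4.37, but 0.05 at percentile 67.7 with the mean of probe sets and −0.006 at percentile 45.6 with the floor at the 75th percentile; Alox5ap and Gpx4 had log2 ratios of 0.05 and −0.06. Of 22 megakaryocyte transcription factors, 2 were at least 2-fold lower. Ldb1 was at least 2.39-fold lower and Srf 2.86-fold lower with disagreeing probe sets (mean log2 ratio −0.45), while Fli1, an ETS factor of the megakaryocyte lineage, read 20079 against 10455 and Mafk had a log2 ratio of 0.70. The median of that list was 0.09 and its mean −0.07, at percentile 78.8 for the median. The 17 genes of apoptosis and platelet lifespan stayed within 2-fold with a median of −0.11 at percentile 21.3, Xiap at −0.18 and Cflar at −0.06.

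Ribosomal protein genes were slightly higher as a group. Of 39 measured, 0 passed 2-fold, 32 had a ratio above 0, and the median log2 ratio was 0.23, at percentile 99.97; the strongest members, Rps29 and Rpl37a, had log2 ratios of 0.12 and 0.11. Glycolysis genes were lower as a group, with a median of −0.30 over 18 genes at percentile 0.76 and 5 genes above 0. The hexokinase gene Hk3 was at least 2.44-fold lower, Pfkl and Pgam1 had log2 ratios of −0.80 and −0.71, and Hk2 had one of 0.73 with Smad4 f/f below the floor. Beside both shifts, the 3' over 5' signal of the Gapdh control probe sets, a sign of RNA quality, was 1.86 in Smad4 f/f and 2.61 in Smad4 −/−, a log2 difference of 0.49. For beta-actin the values were closer, 1.16 and 1.27, a log2 difference of 0.13. T and NK cell markers (median 0.41), endothelial markers (median 0.47) and 6 of 21 erythroid markers were also higher on that array. The medians of B cell (−0.01), monocyte and macrophage (−0.01) and neutrophil markers (0.10) lay inside the central 95% of random lists. Oxidative phosphorylation showed no such shift, with a median of 0.02 over 74 genes at percentile 56.9, 0 genes past 2-fold, Cox5a at −0.05 and Cox6b1 at 0.003.

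Immediate early genes were also higher as a group, with a median of 0.35 over 16 genes at percentile 99.3. The same differences in Gapdh 3' over 5' signal and in some lists of markers of other cells stand beside this shift and that of the chemokine genes. Egr1 was 2.41-fold higher (152 against 366), Gadd45b was at least 2.44-fold higher by 1 probe set and had a log2 ratio of −1.15 by the other (mean 0.07), and Egr3 and Ppp1r15a had log2 ratios of 0.96 and 0.82. In the cluster of CXC chemokine genes around Pf4, 3 of 6 measured genes were at least 2-fold higher and the median was 0.59, at percentile 99.8, but 0.20 at percentile 90.0 with the floor at the 75th percentile and 0.11 at percentile 71.3 with no floor. Cxcl3 read 710.5 against 3044, Cxcl5 257 against 539, and Cxcl2 was at least 2.19-fold higher, whereas Cxcl1 had a log2 ratio of −0.73. Pf4 and Ppbp, near the top of the signal scale, had log2 ratios of 0.04 and 0.11.

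Of 24 interferon-stimulated genes, 2 were at least 2-fold higher and 0 lower. Ifitm1 was 3.29-fold higher and Ifit1 2.89-fold, while Ifi27l2a and Usp18 had log2 ratios of −0.82 and −0.74, and the list median of 0.13 lay at percentile 89.9. In the proteasome, 2 of 38 genes were at least 2-fold lower. Psmd9 was 2.99-fold lower with 2 probe sets in the same direction (mean log2 ratio −0.95), Psmc4 5.59-fold lower with disagreeing probe sets (mean −1.11), and Psmd14 and Psmc5 had log2 ratios of −0.72 and −0.71; the median was −0.04 at percentile 29.4. Of 8 measured genes of the histone list, H1f6 was at least 2.12-fold higher and H3f3a had a log2 ratio of −0.64. H2ax had one of 0.30 and H1f2 one of 0.18, with a list median of 0.01 at percentile 51.9. The symbol pattern of this list does not match H3c11, the histone H3 gene given above as 4.13-fold higher. Histone genes with symbols of that form are therefore not covered by the list. The 22 cell cycle genes stayed within 2-fold with a median of 0.16 at percentile 94.3 (0.34 at percentile 99.5 with the floor at the 50th percentile and 0.39 at percentile 98.8 with none), Ccnd3 at 0.44 and Ccnd1 at −0.78. In the unfolded protein and heat shock response, Pdia4 was the only one of 21 genes past 2-fold, at 2.51-fold higher, with Dnajb1 at −0.94, Hspb1 at 0.65, Dnaja1 at −0.65 and a median of 0.06 at percentile 69.6.

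Several red cell genes were higher in Smad4 −/−. Of 21 measured erythroid markers, 6 were at least 2-fold higher and 0 lower. The mitochondrial iron importer gene Slc25a37 was 3.90-fold higher, Fech, the last enzyme of haem synthesis, 3.06-fold (4551 against 13904) with 3 probe sets in the same direction, Bpgm 2.65-fold, and Alas2, the first enzyme of haem synthesis in red cells, 2.40-fold. Car2 and Slc4a1 were 2.40-fold and 2.36-fold higher. The list median was 0.23, at percentile 96.7 (0.40 at percentile 99.99 with the mean of probe sets and 0.24 at percentile 98.2 with the floor at the 75th percentile), and 2 of the genes, Ank1 and Isg20, stand in other lists too. T and NK cell markers had a median of 0.41 over 15 genes at percentile 99.5, with 14 above 0. Cd28 was 2.74-fold higher (4685 against 12825) and Ccl5, which platelets also carry, 2.02-fold. Cd3d, with a weaker signal (356 against 181), had a log2 ratio of −0.98, so Cd28 and Cd3d went opposite ways. Bcl11b had a log2 ratio of 0.94 with disagreeing probe sets. Ccl5 and Lat stand in other lists too.

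Endothelial markers had a median of 0.47 over 13 genes at percentile 99.8, but 0.16 at percentile 86.9 with the floor at the 50th percentile, 0.11 at percentile 74.97 with none and 0.23 at percentile 96.3 with the mean of probe sets. Flt1, a VEGF receptor gene, was at least 9.38-fold higher by its strongest probe set, with disagreement among its 4 probe sets (mean log2 ratio 1.61), Pecam1, also a platelet gene, read 2203 against 4170 (log2 ratio 0.92), and Robo4 and Erg had log2 ratios of −0.74 and −0.67. Of 19 B cell markers, Jchain was at least 3.73-fold and Cr2 2.33-fold higher, Blk had a log2 ratio of −0.84 and Cd79a one of 0.78, and the median was −0.01 (mean 0.09) at percentile 46.5. Among 14 monocyte and macrophage markers Csf1r was 3.11-fold higher with disagreeing probe sets (mean log2 ratio 0.28), Ms4a6c, Mpeg1 and Ctss had log2 ratios of −0.997, −0.95 and 0.83, and the median was −0.01 (mean 0.11) at percentile 54.9. The 12 neutrophil markers stayed within 2-fold with a median of 0.10 at percentile 83.1, S100a8 at 0.23 and S100a9 at 0.47, as did 9 genes of MHC class II antigen presentation with a median of 0.19 at percentile 83.1, H2-Eb1 at 0.21 and Cd74 at 0.19. Only 2 basophil and mast cell markers were measured, Il4, at least 2.29-fold lower, and Il6ra, with a log2 ratio of 0.86. Among sex-linked transcripts, Xist read 204 in Smad4 f/f and 646 in Smad4 −/−, while the Y-linked Eif2s3y and Uty had log2 ratios of −1.41 and −0.86. By these probe sets Xist, Eif2s3y and Uty lay above the floor on each array, though only 1 of the 3 Xist probe sets was measured. Higher Xist with lower Y-linked signal goes with a larger share of female RNA on the Smad4 −/− array. The sex of the mice is not given in the labels. No difference between the genotypes reported here is separated from a difference in the mix of sexes.

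Of the 28 lists with at least 5 measured genes, 6 lay outside the central 95% of random lists. Of these, 5 lay above (ribosomal proteins, immediate early genes, the chemokine cluster, T and NK cell markers and endothelial markers) and 1 below (glycolysis). For lists of unrelated genes, 1.4 would be placed there by chance. Some lists share genes, and genes of a list can vary together, so the 6 cannot be set against that figure. These percentiles describe the 2 arrays and are not tests. The shift of glycolysis was inside the central range with no floor (−0.24 at percentile 3.37) and with the mean of probe sets (−0.23 at percentile 3.02).

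**Figure D3:**
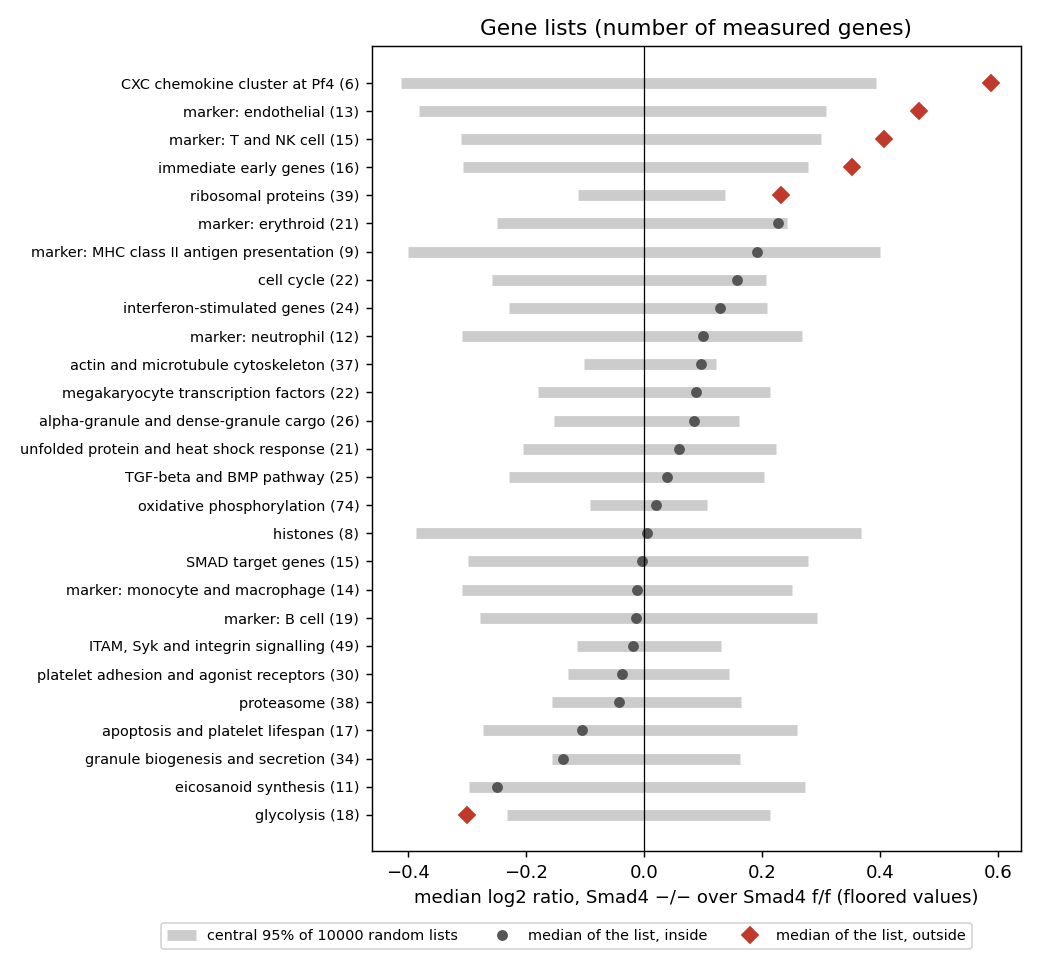
Median log2 ratio of Smad4 −/− over Smad4 f/f for each gene list reported here (points; diamonds lie outside) and the central 95% of 10000 random lists of the same size and matched signal (grey bars), with the number of measured genes in brackets. The chemokine cluster has the highest median, 0.59, and glycolysis the lowest, −0.30.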

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

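No tests were run in this part. Probe sets without a single gene symbol are outside the gene comparisons but carry signal. Of 2717 measured probe sets with no gene symbol, 68 were at least 2-fold higher in Smad4 −/− than in Smad4 f/f, and 96 were at least 2-fold lower. Of 561 measured probe sets with several gene symbols, 18 were at least 2-fold higher in Smad4 −/− and 22 at least 2-fold lower.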

How the results depend on the processing

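The log2 ratio of Smad4 stayed between −0.11 and −0.08 under all 8 alternatives of scaling, floor and probe sets. The counts of genes at least 2-fold higher and lower, 379 and 397, depended on the floor and the threshold: 671 and 762 with the floor at the 50th percentile, 175 and 140 at the 75th, 2727 and 3079 with no floor, 1308 and 1480 at 1.5-fold, and 57 and 46 at 3-fold. A lower floor or threshold admits more genes by construction. The other alternatives kept both counts within 1.5 times, from 287 to 426 higher and from 298 to 390 lower, and the share of higher genes, 48.8%, stayed between 46.8% and 55.6%. Of the 61 named genes past 2-fold, 42 passed it in the same direction in every alternative that gave a value; 14 were short of it with the floor at the 75th percentile, among them Cdkn1a, Fn1, Tbxa2r, Hk3, Egr1 and Cxcl2, and 7 with the mean of probe sets, among them Syk and Smad5. Aplp2 reversed to 0.27 with the mean of its probe sets, which disagree with each other. All 61 stayed past 2-fold under the scaling alternatives, with the floor at the 50th percentile and with no floor. A lower floor cannot bring a ratio back under 2-fold, and the mean cannot change a gene with 1 measured probe set. The count of 42 therefore says little on how these ratios would hold on other arrays. The number of lists outside the central range was 6, 5 with the mean of probe sets and 4 with no floor. Ribosomal proteins, immediate early genes and T and NK cell markers lay outside it in all 8 alternatives, and erythroid markers and cell cycle genes in 2 each. The medians of 14 lists changed sign in at least 1 alternative; all 14 lay inside the central range as reported, and 0 of the changes took a list outside it. No paired analysis was possible because each genotype has 1 array. Signals near the floor limit the ratios of weak genes to lower bounds.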

Other observations

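All tests of explanations in this part, the scaling alternatives for strongly expressed genes and the choice of the genes named in the next paragraph were made after the results were seen. Each test compares the same 2 arrays.

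Among the 1201 genes with a mean log2 signal of 12 or more, 33 were at least 2-fold higher in Smad4 −/− and 10 at least 2-fold lower. At a mean log2 signal of 7 to 8, 136 genes were higher and 172 lower by as much, and at 8 to 9, 90 and 111. The strong-signal counts were 33 and 10 after median centring and after the loess correction, and 32 and 11 after quantile normalisation. Pink1, a kinase of mitochondrial quality control, was 3.76-fold higher (10841 against 40794), the phosphodiesterase gene Pde7b 3.60-fold with 3 probe sets in the same direction, and Capn3, a calpain, 3.35-fold. Tent5c, a poly(A) polymerase, was 2.91-fold higher, Cat, which encodes catalase, 2.41-fold (32029 against 77331), the retinaldehyde dehydrogenase gene Aldh1a1 2.32-fold, Zwint 2.25-fold with 6 probe sets in the same direction, and Ramp1 2.13-fold with 3. Measured probe sets went as low as log2 ratios of 0.76 for Pde7b, 0.95 for Cat, 0.27 for Zwint and 0.87 for Ramp1, short of 2-fold. The 33 also include Fech and Bpgm of the erythroid list and Cd28 of the T and NK cell list. On the lower side, Cd226 was 5.06-fold lower, Ccdc32 3.04-fold and the pseudogene Hmga2-ps1 2.96-fold (72047 against 24326). Oxr1, an oxidation resistance gene, was 2.34-fold lower, Cap2, an actin regulator, 2.22-fold, the endocytic adaptor gene Ston2 2.12-fold and Mctp1 2.08-fold (42691 against 20561). The other measured probe sets of Oxr1 and Ston2 had log2 ratios of −0.96 and −0.38, short of 2-fold.

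The near equal Smad4 signal may come from probe sets outside the deleted part of the gene. The lowest log2 ratio among the 3 probe sets was −0.13, and without their place in the gene this cannot be told apart from mRNA that was not reduced. Swapped arrays were tested through the Cre control probe sets, whose log2 ratio minus that of the other hybridisation spike-ins was −0.13. Cre RNA is itself spiked into the hybridisation mix, so that value decides nothing and a swap stays open. A transcript left after the deletion is a biological explanation that was not tested.

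The 6 erythroid genes past 2-fold had a median log2 ratio of 1.33 (SD over genes 0.29). After the loess correction their median was 1.34, which could hardly have come out otherwise. The median log2 ratio of measured genes ran only from −0.05 to 0.02 over the levels of signal. A trend with signal of that size, left by the authors' scaling, is too small to account for these genes. More red cell or reticulocyte RNA left in the washed platelets of Smad4 −/− mice could raise them, and the globin probe sets bear on this. The 4 globin probe sets more than 1 log2 unit below the highest signal had a median of −0.20 (SD 0.79). Of these 4, 1 read 86681 in Smad4 f/f and 84885 in Smad4 −/− and may be saturated too. The others had log2 ratios of −0.38, −0.97 and 0.91. The 3 nearer the top, with signals up to 138874, lay between 0.10 and 0.21, where the signal may be saturated. The other measured erythroid markers had a median of 0.09 (SD 0.51). This source therefore stays open, as does a difference between the genotypes in the megakaryocytes, which was not tested.

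Cxcl3, Cxcl5 and Cxcl2 were at least 2-fold higher, with a lowest log2 ratio of 1.07. The 14 neutrophil and monocyte markers with a mean log2 signal of at least 8.02 had a median of 0.15 (SD 0.65) and a highest value of 1.635. S100a8 and S100a9, at 3733 and 3343 in Smad4 −/−, had log2 ratios of 0.23 and 0.47. As a set these markers rose less than the chemokine genes, which argues against a general rise of that size in RNA of those cells. The 3 chemokine genes were taken because they passed 2-fold, so their lowest ratio is large by choice. A rise of the chemokine transcripts alone within those cells was not tested, and these markers cannot show it. The signal cut lies near the floor of 7.18, so a smaller share from those cells stays open. Extra copies of neighbouring genes carried with the Cre transgene could raise Cxcl5, Ppbp and Cxcl3, whose log2 ratios had a median of 1.07, but Ppbp was at 0.11 and Pf4 itself at 0.04, both near the top of the signal scale. Of the genes farther off, Cxcl1 was at −0.73 and Cxcl2 was at least 2.19-fold higher. The transgene goes with the genotype in these arrays, so this cannot be told apart from an effect of the loss of Smad4.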
